A study of Aegilops tauschii x Triticum turgidum and Aegilops tauschii and Triticum turgidum subsp. durum with 18 samples.

How the data were processed

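RNA from whole wheat plants of 40 days was measured on 18 Affymetrix GeneChip Wheat Genome arrays, 1 RNA sample per array. Per the labels' protocols, plants grew under a 16 h photoperiod at 24 °C, 98% hygrometry and 10000 lux, 20 or 40 µg of total RNA was used per sample, and 20 µg of biotin-labelled cRNA was hybridised. The 20 µg amount is given for both Ae36 arrays and for Ae54 replicate 2, and 40 µg for the other arrays.

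The values are log2 expression values, 1 per probe set and array, which the authors made with GCRMA, per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalises the arrays to a shared distribution and summarises the probes of a probe set. Its version and settings are not given in the sources used here. Its background model holds unexpressed probe sets near a floor, so a difference from a group near that floor understates the change. The deposited table holds 61290 probe sets, and no column of values was left without a sample. The 111 control probe sets were left out of the tests, which leaves 61179.

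Groups were taken from the sample labels: 9 groups of 2 arrays. The labels call the arrays of 7 groups biological replicates, and those of the RNA mixes only replicates. The organism field of Ae54 replicate 1 names the hybrid, and every sample carries the genotype label hexaploid, so the groups rest on the other label fields. Before averaging, replicate arrays were compared over the tested probe sets. The 2 arrays of mix36 differed by an SD of 0.131 and those of mix54 by 0.117 on the log2 scale, against 0.460 to 0.671 in the other groups. The correlation within a mix was 0.998 for both mixes, against 0.959 to 0.976 elsewhere. Each pair of mix arrays was therefore averaged and counted as 1 sample, after its agreement had been seen, which leaves 16 samples in the fit. The fit laid down before the data were examined counts the mix arrays separately, and its counts of probe sets passing are printed beside the averaged ones. The tests, the filter, the rule for named genes and the other alternatives were also chosen before the data were examined.

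Probe sets with a log2 value of 5 or more on at least 2 arrays were tested, 18189 in all. One linear model with a mean for each of the 9 groups was fitted per probe set with limma 3.58.1 in R 4.3.3, and comparisons were tested with moderated variances (eBayes), two-sided, with 7 residual and 3.44 prior degrees of freedom. Each group holds at most 2 samples, so the spread was estimated over all groups together. Benjamini-Hochberg adjustment was applied within each comparison, and a probe set passed at an adjusted p under 0.05. Standard errors (SE) are those of the fit. The mixes add no plant-to-plant spread of their own. The p-values treat a mix as 1 sample with the spread of the plant groups. For arrays, their number limits the precision.

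A probe table pairs 1273 probe sets with 1 gene symbol, none with several, and lists no gene for 60017. Among the tested probe sets, 716 carry 1 of 511 symbols, and 9 carry a symbol that is not a LOC identifier. Genes are named from this table only, and no function was assigned to a LOC identifier. The rule for named genes took, in each comparison, probe sets past the threshold with an absolute log2 difference of 1 or more, with all arrays of one side above all of the other, and with exactly 1 gene name. It kept the 12 largest rises and the 12 largest falls, 1 probe set per gene, up to 12 genes passing in both crosses, and members of fixed gene lists. Chance alone would leave 2 arrays against 2 without overlap in 33.3% of cases. SAHH and GAPN were added after their values were seen, as were genes named from counts of 5 or fewer. The 21 gene lists fixed beforehand, on photosynthesis, stress, cell wall, chromatin and other themes, were matched to symbols. None had 5 tested probe sets and 3 had 1 each (petC, FBP and CAT1), so no list test was run.

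The position of a sample between its parents was computed as an Ae weight. For each array and probe set, the linear value minus the Joyau mean was divided by the Ae mean minus the Joyau mean. The weight is the median of this ratio over the probe sets called between these parents with an absolute log2 difference of 1 or more. A weight of 0 is Joyau and 1 is Ae. Groups were compared by an exact permutation test, two-sided. Expression classes set each synthetic against each parent in the same fit. Where 2 comparisons share the same mix, the overlap was set against simulated unchanged groups that share it.

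The scripts were tested on simulated data for 18189 probe sets with 200 changed. For S0_36 minus mix36, 5% of log2 changes of 1 and 62% of changes of 2 were recovered, with 4 unchanged probe sets called. For S1_54 minus S0_54 these shares were 29% and 80%, with 5 unchanged probe sets called. For Courtot against the synthetics they were 42% and 89%, with 11. The simulated noise was independent between probe sets and arrays. These numbers therefore need not hold where a difference between arrays is shared by many probe sets. Far fewer probe sets were changed than passed in the data, where these 3 comparisons called 2360, 1662 and 4806. The Benjamini-Hochberg adjustment is looser where more probe sets change, so the recovered shares need not be those of the data. Simulated Ae weights of 0.333 and 0.5 came back as 0.336 and 0.503.

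Alternatives were no filter, a filter on mean values, quantile normalization, fits of only the compared groups, an intensity trend with a robust prior, array weights, an added difference threshold, 1 variance for all probe sets with Bonferroni adjustment, mid-parents computed from the parental arrays, a replicate block, other settings of the Ae weight and leaving out each array. The planned fit with separate mix arrays was kept as an alternative once the averaging had been chosen, after seeing the data. A centring of arrays on the median of the tested probe sets was also added after seeing the data. Genome coordinates and chromosome assignments of the probe sets were not used here.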

Results

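Transcript levels were measured in whole 40-day plants of synthetic hexaploid wheats, their parents and a natural hexaploid wheat. Synthetic hexaploids combine the genomes of a tetraploid wheat and of the diploid goat grass Aegilops tauschii, the 2 progenitors of bread wheat. The tetraploid parent was Triticum turgidum cultivar Joyau. The diploid parents were Ae. tauschii accession 36 (ssp. strangulata, here Ae36) and accession 54 (ssp. tauschii, here Ae54). S0_36 and S0_54 denote the hybrids at selfed generation 0 from accessions 36 and 54, and S1_54 denotes selfed generation 1 from accession 54. Mixes of equal amounts of Joyau and Ae36 RNA (mix36) or Joyau and Ae54 RNA (mix54) served as reference. A hexaploid holds more of its genome from the tetraploid than from the diploid parent, so an equal mix need not be its additive level. A difference from a mix is therefore not by itself a departure from additivity. The natural hexaploid was Triticum aestivum cultivar Courtot. Each of the 9 groups had 2 arrays. The 2 arrays of a mix differed far less than those of any plant group and were counted as 1 sample.

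Values spanned 1.24 to 15.54 on the log2 scale, with array medians between 2.86 and 3.04 over all probe sets. Between 11733 and 14025 probe sets per array reached a log2 value of 5. The first principal component of the 18189 tested probe sets held 48.4% of the variance and ran from Joyau, with a mean score of -127, to Ae36 at 168 and Ae54 at 152. The synthetics lay nearer to Joyau, at -41.5 for S0_36, -39.9 for S0_54 and -55.9 for S1_54, with Courtot at -23.7. Of the mixes, mix54 at -36.4 lay close to S0_54, and mix36 was at 4.89. The second component held 14.1% and set the synthetics, at 26.2 to 78.0, apart from the mixes, at -31.4 and -49.7.

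**Figure D1:**
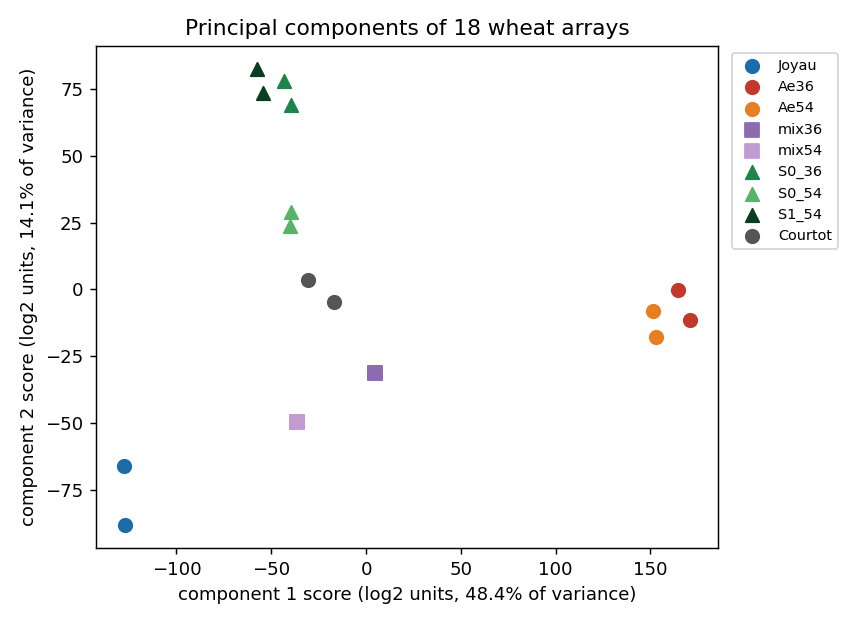
Scores of the 18 arrays on the first 2 principal components of the tested probe sets (log2 units), 1 point per array, with squares for mixes, triangles for synthetics and circles for parents and Courtot. Component 1 (48.4% of the variance) runs from Joyau to the 2 Ae. tauschii accessions, and on component 2 (14.1%) the synthetics lie above the mixes.

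The parental comparisons asked how the tetraploid and diploid progenitors differed. LOC100037539 was higher in Joyau than in Ae36 by 10.72 ± 0.18 on the log2 scale (SE, adjusted p = 8.1e-11), with a mean of 13.30 ± 0.05 (SD, n = 2 arrays) in Joyau against 2.59 in Ae36, and LOC606340 was higher in Joyau by 8.30 than in Ae36 and by 8.22 than in Ae54. In the other direction, LOC542997 was at 2.81 in Joyau and at 12.66 in Ae36, a difference of -9.84 ± 0.37, and was lower in Joyau than in Ae54 by -9.32. LOC543254 was likewise lower in Joyau, by -9.52 against Ae36 and -8.92 against Ae54. Probe sets of LOC606328 went opposite ways: Ta.6572.1.S1_at was higher in Joyau by 7.72 and Ta.6572.2.S1_at lower by -7.31 against Ae36. The gene's further tested probe set, Ta.6572.1.S1_a_at, is not described here. Between Joyau and Ae36, 10839 of the 18189 probe sets passed, 5865 higher and 4974 lower in Joyau. Between Joyau and Ae54, 10170 passed, 5417 higher and 4753 lower. The balance turned after quantile normalization, to 5490 higher and 5645 lower against Ae36 and 5048 and 5459 against Ae54, and after centring each array on its median, to 5373 and 5783 and to 5082 and 5431. With separate mix arrays, which changes the estimate of the spread, 11724 and 11138 passed. These comparisons cross species, so a difference in probe match may raise or lower a measured difference. Probe match was not measured.

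The accessions also differed from each other. LOC542898 was higher in Ae36 than in Ae54 by 7.88, with means of 12.44 ± 0.22 and 4.56 ± 0.04 (SD, n = 2 each). LOC606323 was higher in Ae36 by 7.43 and LOC543196 by 5.53. LOC100037599 was higher in Ae54, at a difference of -4.51 ± 0.45 (SE, adjusted p = 5.61e-05), and LOC542847 at -3.78 ± 0.26. In all, 3322 probe sets passed, 1599 higher and 1723 lower in Ae36. The balance turned with no filter (1912 and 1698), after centring each array on its median (1844 and 1760) and with 1 variance and Bonferroni adjustment (586 and 570). It did not turn after quantile normalization (1713 and 1842) or with array weights (947 and 997). With separate mix arrays 4512 passed, with array weights 1944, and with only these 2 groups in the fit 1057.

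The comparison of S0 plants with the mixes asked which transcripts departed from the level of an equal RNA mix. Named genes that passed in the same direction in both crosses numbered 26. LOC606312 was at 11.13 ± 0.10 in S0_36 and 11.38 ± 0.01 in S0_54 (SD, n = 2 each), above Joyau at 8.67, Ae36 at 3.21, Ae54 at 2.99 and the mixes at 7.78 and 8.19. It rose by 3.27 ± 0.21 over both crosses (SE, adjusted p = 4.19e-06). LOC778394 rose by 4.68 ± 0.65 on its probe set Ta.10532.1.A1_s_at. Its other probe set TaAffx.105521.1.S1_at was near the floor in the 3 parents and both mixes, at 2.52 to 2.95, and at 8.08 ± 1.23 in S0_36 and 6.40 ± 1.46 in S0_54. LOC543416, LOC543368 and LOC543244 fell. LOC543416 was at 7.86 ± 0.10 in Joyau and at 7.03 and 7.66 in the mixes, but at 3.50 in S0_36 and S0_54, beside 3.64 in Ae36 and 3.59 in Ae54, so that it fell by 3.84 (SE 0.14, adjusted p = 1.8e-07). LOC543368 and LOC543244 changed by -3.25 and -3.01, likewise to levels close to or below those of the Ae parents.

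CAT1, which encodes catalase, the enzyme that breaks down hydrogen peroxide, was the only member of a list fixed beforehand that passed against a mix. It fell by 1.97 over both crosses (adjusted p = 0.000147), with -2.18 ± 0.30 in S0_36 and -1.76 in S0_54, and its S0 levels of 10.03 ± 0.12 and 10.88 ± 0.31 (SD, n = 2 each) lay below Joyau at 12.89, Ae36 at 11.09 and Ae54 at 11.92. The other list members tested did not pass over both crosses: FBP was at 0.66 and petC at -0.17. SAHH, which encodes S-adenosylhomocysteine hydrolase, an enzyme of the methyl cycle, fell by 1.65 (adjusted p = 0.00322) with -1.79 on its other probe set. It stood at -1.05 in S0_36, which did not pass, and at -2.24 in S0_54, where mix54 at 12.52 lay above both parents, the higher of which was Joyau at 11.87. GAPN, a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, fell by 1.00 (adjusted p = 0.0246), with -1.26 in S0_36 and -0.74 in S0_54, and passed in neither cross alone. Over both crosses 3578 probe sets passed, 1376 higher and 2202 lower in S0. The count was 7194 with the mix arrays as separate samples and 6510 against a computed 1:1 mid-parent. With 1 variance for all probe sets and Bonferroni adjustment the balance turned, with 645 higher and 367 lower.

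**Figure D2:**
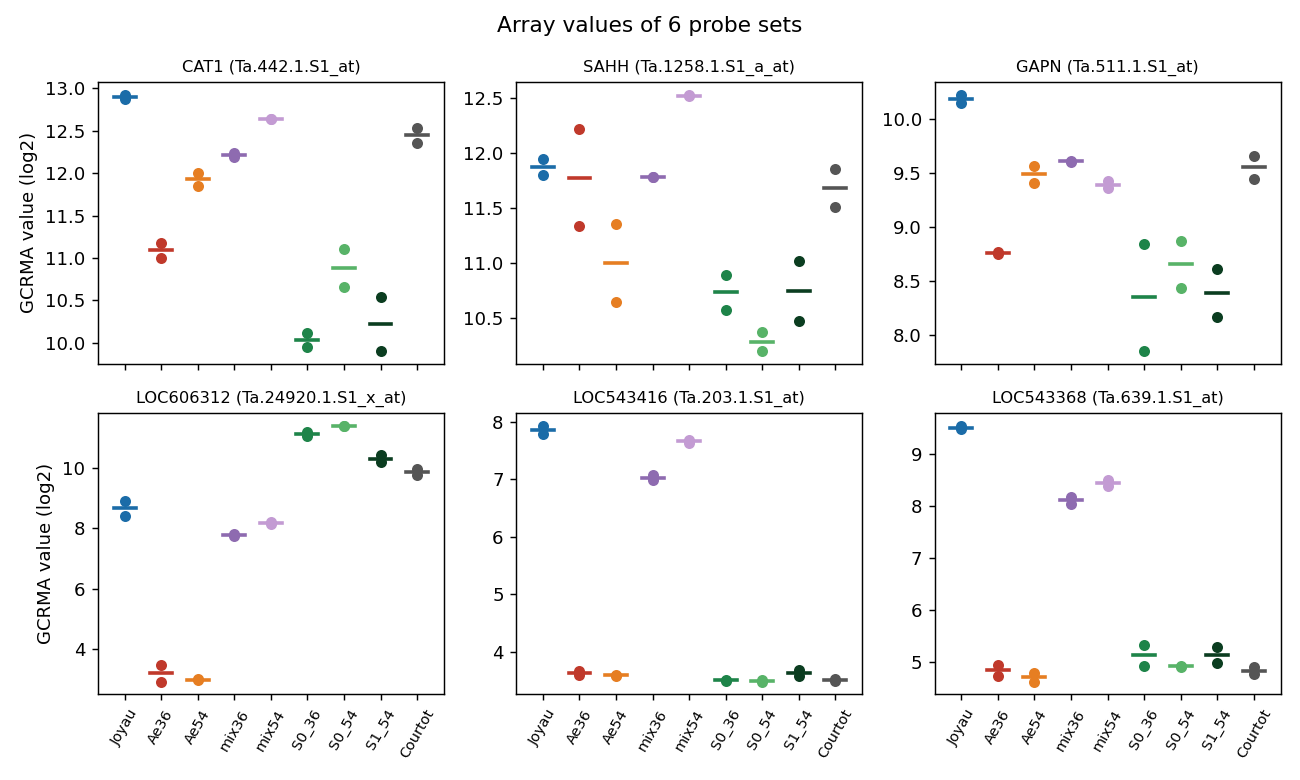
GCRMA values (log2) of 6 probe sets on each array, 1 point per array, by group. LOC606312 lies above both parents in the 3 synthetic groups, LOC543416 falls from 7.86 in Joyau to 3.50 in both S0 groups, and CAT1 lies below both parents in the 3 synthetic groups.

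In the cross with accession 36, LOC778394 (Ta.10532.1.A1_s_at) rose by 5.74 ± 0.91 (SE, adjusted p = 0.00261). LOC100125738 rose by 4.33, LOC542826 by 3.91 and LOC100049023 by 3.77. LOC543016 fell by 5.55 (SE 1.56, adjusted p = 0.0418), from 8.37 in mix36 and 9.82 in Joyau to 2.83 ± 0.01 in S0_36 (SD, n = 2), a call that ended with array weights. LOC100125731 and LOC543416 changed by -3.54 and -3.53. In total 2360 probe sets passed, 1142 higher and 1218 lower (732 and 149 with 1 variance and Bonferroni adjustment, 675 and 297 with only these groups in the fit), with a median log2 difference of -0.136 over all tested. The count was 5598 with separate mix arrays, 4936 and 4679 against computed mid-parents of 1:1 and 2:1, 972 with only these groups in the fit, where LOC542826 did not pass, 1319 without S0_36 replicate 3 and 1525 without S0_36 replicate 9.

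In the cross with accession 54, LOC542888 rose by 4.58 ± 0.76 (SE, adjusted p = 0.00441), from 2.96 in mix54 to 7.54 ± 0.53 in S0_54 (SD, n = 2). LOC606323 rose by 3.79, LOC606312 by 3.19 and LOC606310 by 2.92. LOC543416 fell by 4.16 ± 0.20 (adjusted p = 3.33e-06), with -3.53 for LOC543368, -3.46 for LOC542820 and -3.37 for LOC543244. For LOC542820, mix54 at 9.08 lay above Ae54 at 8.09, the higher parent, while S0_54 at 5.62 lay below both parents. Some of the largest differences followed the level of mix54 itself. LOC542989 rose by 5.62, but mix54 was at 5.70, below both Joyau at 6.46 and Ae54 at 10.06. LOC606328 (Ta.6572.2.S1_at) rose by 4.10 against mix54 and stood at -0.19 against a computed 1:1 mid-parent. LOC543317 fell by 4.64 from 9.16 in mix54, above Joyau at 3.43 and Ae54 at 7.26, and its call ended against the computed mid-parents. In total 1753 probe sets passed, 726 higher and 1027 lower. This balance turned with 1 variance and Bonferroni adjustment, to 294 higher and 240 lower, but not after quantile normalization, with 872 and 1095. The count was 4442 with separate mix arrays, 2889 and 2667 against computed mid-parents of 1:1 and 2:1, 910 without S0_54 replicate 3 and 845 without S0_54 replicate 4. With only S0_54 and mix54 in the fit, which leaves 1 residual degree of freedom, limma called 0 probe sets, while 5527 had an unadjusted p under 0.05.

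Between the crosses, 343 probe sets were called higher than the mix in both and 428 lower in both, against 45.6 and 68.8 for independent lists, while 48 were called in opposite directions against 113. The S0 minus mix differences correlated at r = 0.457 across probe sets, which are not independent replicates, and at -0.0124 in simulated unchanged groups. That simulation and the counts for independent lists take the mixes as independent references. Both mixes hold Joyau RNA, and their deviations from the computed mid-parents correlated at 0.270, so part of the overlap may come from the mixes.

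**Figure D3:**
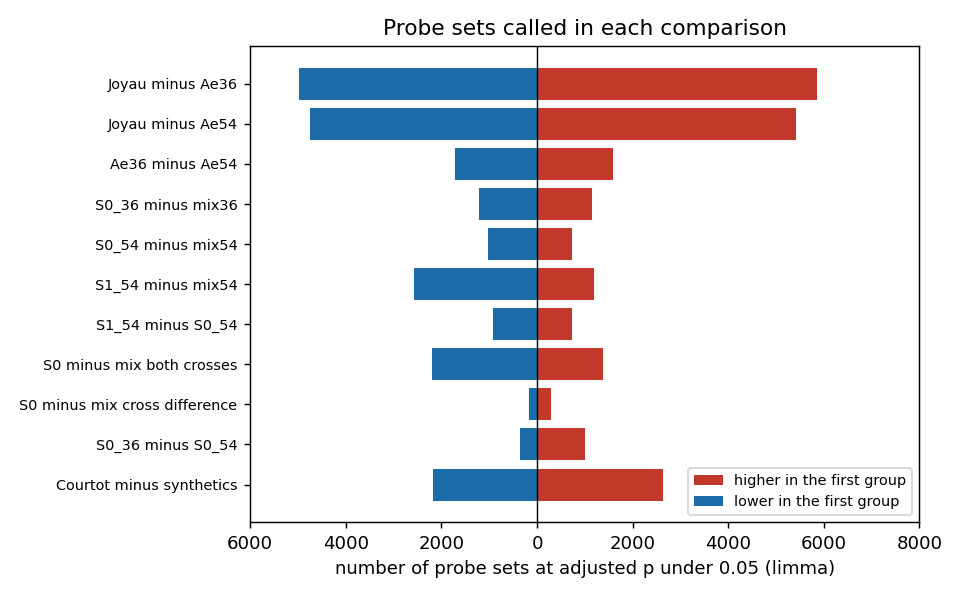
Number of probe sets at an adjusted p under 0.05 (limma) in each comparison, with those higher in the first group to the right of 0 and those lower to the left. The parental comparisons call 10839 and 10170 probe sets, the S0 against mix comparisons 2360 and 1753.

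The difference between the crosses was tested directly. LOC542826 rose in S0_36 by 3.91 against mix36 and was at -0.95 against mix54 in S0_54, a difference of 4.86 ± 0.65 (SE, adjusted p = 0.00377). LOC100049055 differed by 3.96, LOC543476 by 3.69 and LOC543201 by 3.51. LOC543003 differed by -3.44 ± 0.69, at -2.61 in S0_36 and 0.82 in S0_54. In all 450 probe sets passed, 291 higher and 159 lower in cross 36. With only the S0 and mix groups in the fit, LOC542826, LOC543476 and LOC543003 did not pass. The count was 1945 with separate mix arrays, 774 with array weights, 248 without S0_36 replicate 3, 282 without S0_54 replicate 3 and 277 without S0_54 replicate 4.

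Compared directly, S0_36 and S0_54 differed in LOC542898, which was at 11.38 ± 0.24 in S0_36 and 4.04 ± 0.04 in S0_54 (SD, n = 2 each), a difference of 7.34 ± 0.25 (SE, adjusted p = 5.28e-08), next to 12.44 in Ae36 and 4.56 in Ae54. LOC543196 was higher in S0_36 by 4.31, LOC543476 by 3.66 and LOC606323 by 3.61. LOC543184 was lower in S0_36, by -3.08. In all 1359 probe sets passed, 1011 higher and 348 lower in S0_36, with a median of -0.125 over all tested. The differences correlated at r = 0.386 across probe sets with the difference between the 2 Joyau arrays. The count was 2190 with separate mix arrays, 1392 higher and 798 lower, and 2766 with array weights. It was 605 without S0_36 replicate 3, 688 without S0_54 replicate 3 and 696 without S0_54 replicate 4.

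In generation 1 of the cross with accession 54, LOC543416 again fell by 4.02 ± 0.20 against mix54 (SE, adjusted p = 4.85e-06), with -3.31 for LOC543368, -3.27 for LOC543244 and -3.46 for LOC542820. CAT1 fell by 2.41 (adjusted p = 0.000687), to 10.22 ± 0.45 (SD, n = 2). LOC543422 fell by 6.37 ± 1.10, from 11.52 in mix54, where Joyau was at 7.92 and Ae54 at 8.64, to 5.16, and LOC543498 changed by -3.95. LOC780692 rose by 3.27 ± 0.42 and LOC100037634 by 2.45. For LOC100037634, mix54 at 4.01 lay below Joyau at 4.47, the lower parent, and S1_54 at 6.46 lay near Ae54 at 6.04. For LOC543498, mix54 at 6.55 lay above Joyau at 5.68, the higher parent. For LOC542820, mix54 at 9.08 lay above Ae54 at 8.09, the higher parent. The differences of these genes therefore rest in part on the level of mix54. Of the 3761 probe sets that passed, 1188 were higher and 2573 lower in S1_54, so 68.4% were lower, beside a median of -0.267 over all tested. The differences correlated at r = 0.457 across probe sets with the difference between the 2 Joyau arrays, as against 0.287 for S0_36 minus mix36 and -0.0268 for S0_54 minus mix54. With 1 variance and Bonferroni adjustment 667 were higher and 382 lower. After quantile normalization 58.5% were lower (1455 higher, 2049 lower) and after centring each array on its median 51.7% (1546 higher, 1652 lower). The count was 7417 with separate mix arrays, 6555 and 6196 against computed mid-parents of 1:1 and 2:1, and 1784 without S1_54 replicate 5. With only S1_54 and mix54 in the fit limma called 0 probe sets, while 5723 had an unadjusted p under 0.05. S0_54 and S1_54 share mix54 as reference: 464 probe sets were higher in both, 863 lower in both and 1 opposite, against 47.4, 145 and 170 for independent lists. The differences correlated at r = 0.658, against 0.673 in simulated unchanged groups sharing mix54, with a covariance of 0.677 against 0.166. The mix could not be divided, so part of the overlap may come from it.

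Between the generations, LOC542888 fell by 4.68 ± 0.62 (SE, adjusted p = 0.00435), from 7.54 ± 0.53 in S0_54 to 2.86 ± 0.15 in S1_54 (SD, n = 2 each), the level of Ae54 at 2.83. LOC606323 fell by 2.94, from 7.88 to 4.94. LOC542781 rose by 2.27 ± 0.31, from 10.41 to 12.68. These 3 were the only ones of 24 named genes whose calls held at both ends of the range obtained when 1 array was left out. In all 1662 probe sets passed, 738 higher and 924 lower in S1_54. This balance of 55.6% lower turned to 33.3% after centring each array on its median, with 945 higher and 472 lower, and was 44.6% after quantile normalization, with 846 higher and 680 lower. The median over all tested probe sets was -0.221. Only 96 passed without S1_54 replicate 5, 145 without S0_54 replicate 3 and 360 without S0_54 replicate 4. With separate mix arrays 3269 passed, with array weights 3708 and with only these groups in the fit 614. The S1_54 minus S0_54 differences also correlated at r = 0.627 across probe sets with the difference between the 2 Joyau arrays. Of the 1662 called probe sets, 1279 had the same sign in both. With the replicate differences of Ae36, Ae54 and Courtot in place of Joyau, 1090, 1070 and 925 did. The Joyau difference had a negative median too, at -0.135, and such a shared shift can by itself raise these counts. The S1_54 arrays had hybridization controls at 10.26, against 9.16 in S0_54, and an 18S rRNA control at 8.23 ± 0.47, against 4.82 ± 0.96 (SD, n = 2 each).

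The natural hexaploid was compared with the mean of the 3 synthetic groups. LOC780572 was at 7.33 ± 0.37 in Courtot (SD, n = 2) and at 2.32 to 3.29 in every other group, higher by 4.54 ± 0.33 (SE, adjusted p = 3.4e-06). LOC543418 was higher by 4.10 and LOC606341 by 3.53. LOC543352 was at 2.49 ± 0.08 in Courtot and at 6.76 to 7.02 in every other group, lower by -4.40 ± 0.17 (adjusted p = 2.42e-08). LOC778394 was lower in Courtot by -4.62, at 2.87 against 3.08 in Joyau, so the level seen in the synthetics was not seen there. CAT1 was higher in Courtot by 2.06 (adjusted p = 3.35e-05), at 12.44 ± 0.12, and GAPN by 1.09 (adjusted p = 0.0103). LOC543416 was at 3.51 ± 0.02, as low as in the synthetics. In all 4806 probe sets passed, 2633 higher and 2173 lower in Courtot (2481 and 2543 after centring each array on its median), 6397 passed with separate mix arrays, and 1996 passed without Courtot replicate 1. Courtot was the only natural hexaploid measured, so these differences hold for this cultivar.

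Each synthetic was also placed against both of its parents. In S0_36, 4147 probe sets matched Joyau and differed from Ae36 (Joyau-like), 2171 were Ae-like and 2595 lay between the parents. A further 962 were above both parents, LOC606312 among them, and 585 below both, CAT1 among them. In S0_54 these classes held 3943, 1974, 2178, 496 and 291 probe sets, and in S1_54 they held 4222, 2017, 2318, 893 and 1308. CAT1 was below both parents in all 3 synthetic groups, by -1.06 against Ae36 in S0_36, and by -1.04 and -1.70 against Ae54 in S0_54 and S1_54. Several classes moved by more than 1.5 times when 1 array was left out. The below-both class of S0_36 held 269 without S0_36 replicate 9, 302 without S0_36 replicate 3, 321 without Joyau replicate 1 and 387 without Joyau replicate 2. That of S0_54 held 110 without S0_54 replicate 3, 161 without S0_54 replicate 4 and 164 without Ae54 replicate 1, and that of S1_54 held 616 without S1_54 replicate 5 and 752 without Joyau replicate 1. The above-both class of S0_54 held 315 without Joyau replicate 2 and 317 without S0_54 replicate 4, and that of S1_54 held 527 without S1_54 replicate 5 and 593 without Joyau replicate 1. The class between the parents held 1707 and 1689 in S0_36 without S0_36 replicates 3 and 9, and 1275 and 1167 in S0_54 without S0_54 replicates 3 and 4. The Ae-like class of S0_54 held 1299 without Joyau replicate 2. A probe set that did not differ from a parent by the test is not shown to equal it.

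The mixes were set against the mean computed from the parental arrays. The median difference was -0.0836 in mix36 and -0.0105 in mix54 on the log2 scale. In mix54, 224 probe sets lay at least 1 log2 unit above both parents, LOC543317 among them at 9.16, and 44 did in mix36. Over probe sets that part the parents, the Ae weight was 0.552 in mix36 and 0.375 in mix54, so the mixes did not hold the same share of Ae signal. It was 0.380 in S0_36, 0.373 ± 0.013 in S0_54 and 0.351 ± 0.002 in S1_54 (SD, n = 2 each), and 0.396 or 0.415 in Courtot against the pair with Ae36 or Ae54. Split by the parent with the higher level, the weight of S0_36 was 0.533 over probe sets higher in Joyau and 0.243 over those higher in Ae36, against 0.581 and 0.485 in mix36. In S0_54 these weights were 0.477 and 0.292 and in S1_54 0.577 and 0.170, against 0.406 and 0.312 in mix54. In Courtot they were 0.549 and 0.259 for the pair with Ae36, and 0.549 and 0.286 for the pair with Ae54. The S0 groups lay below the mixes by -0.0867. In the weight over all of these probe sets the gap came from cross 36. It was -0.0366 under the filter on mean values and -0.000371 on the log2 scale. The test could not pass at 0.05 (exact permutation test, two-sided, p = 0.267, 15 arrangements, smallest possible p 0.0667). With the mix arrays counted separately p was 0.286 (exact permutation test, 70 arrangements, smallest possible p 0.0286). Both tests exchanged arrays across the crosses and so ignored the difference between the 2 mixes.

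**Figure D4:**
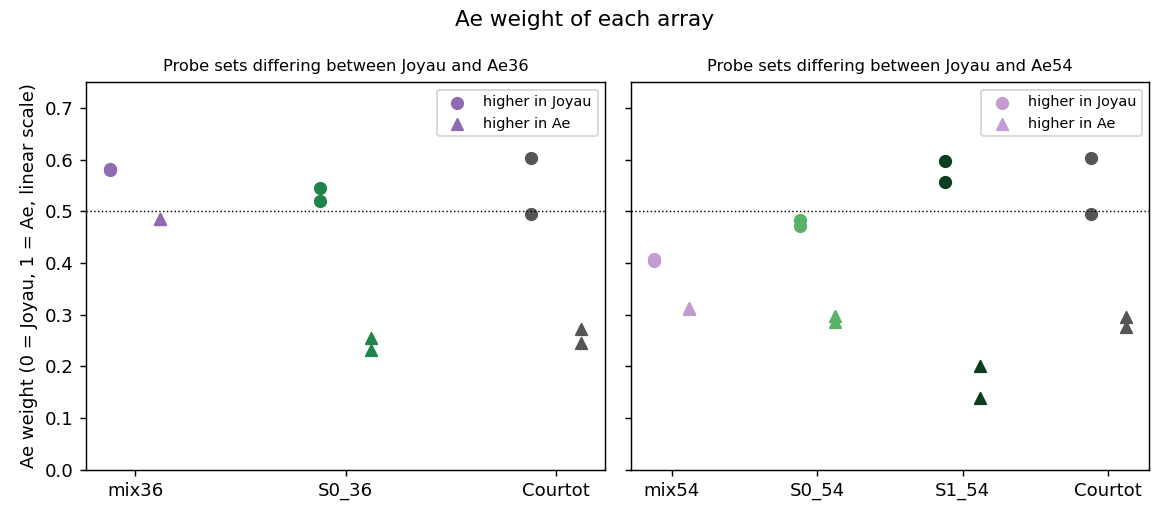
Ae weight of each array (0 is Joyau, 1 is Ae, linear scale), 1 point per array, for the pair with Ae36 on the left and with Ae54 on the right, over probe sets higher in Joyau and higher in Ae separately. In the synthetics the weight is lower over probe sets higher in Ae, at 0.243 in S0_36, 0.292 in S0_54 and 0.170 in S1_54. It is also lower there in the mixes and in Courtot.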

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

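The tests of the mix54 values, of the gradient shared with the Joyau arrays and of unequal RNA amounts were chosen only after the results were seen, and the measure and bounds of the test of the mix54 values were changed again after its outcomes were seen. The others were laid down before.

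The difference between S0 and its RNA mix was not the same in the 2 crosses for 450 probe sets, by the test of the difference itself. Of these, 288 also passed against the 1:1 mid-parents computed from the parental arrays and 273 against the 2:1 mid-parents. LOC542989 had nearly equal S0 levels, at 12.82 in S0_36 and 12.94 in S0_54, while mix36 was at 11.87 and mix54 at 8.32, with Ae54 at 12.15. As cross 36 minus cross 54 on the log2 scale, the S0 minus mix difference was 4.86 for LOC542826, 3.96 for LOC100049055, 3.69 for LOC543476, 3.51 for LOC543201, 3.17 for LOC543197, 3.14 for LOC542847, 2.78 for LOC100049023, 2.76 for LOC543182, 2.66 for LOC778392, 2.50 for LOC542829, 2.41 for LOC543369 and 2.34 for LOC542999. It was -4.17 for LOC543145, -3.84 for LOC100125731, -3.67 for LOC542989, -3.44 for LOC543003, -3.02 for LOC100125715, -2.86 for LOC543338, -2.60 for LOC542812, -2.58 for LOC543184, -2.11 for LOC543127 and -1.996 for LOC780574. The calls of 11 of these 22 genes ended at an end of the range obtained when 1 array was left out: LOC100049023, LOC543182, LOC778392, LOC542829, LOC543145, LOC100125731, LOC542989, LOC100125715, LOC542812, LOC543184 and LOC543127. Among the control probe sets outside the comparisons, 18S rRNA was brightest in S1_54, with a mean of 8.23 ± 0.47 (SD, n = 2), against 7.55 ± 0.85 in Ae36, 6.79 ± 0.98 in Joyau, 6.62 in Ae54 and 4.82 to 5.93 in the other groups. Replicate 2 of Ae36, at 8.15, lay above S1_54 replicate 7, at 7.90.

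S1_54 had more probe sets lower than mix54 than S0_54 had, and lay apart from S0_54. Chance values of the mix54 arrays enter both comparisons alike and not S1_54 minus S0_54, so the 2.58 times as many lower probe sets in S1_54 against the mid-parent computed from the parental arrays (4862 and 1888) decide nothing about them, and the numbers against mix54 were 2573 and 1027, 1116 and 935 without S1_54 replicate 5, and 1652 and 1052 after centring. Weak hybridization of the S1_54 arrays stays open: in 3 other groups the array with the brighter hybridization controls shifted by -0.0770 on average over the probe sets lower in S1_54, with -0.0432 in Joyau and -0.0187 in Courtot, which met the bound of -0.05 against it, and -0.169 in Ae36, which met neither bound, and brighter minus dimmer array correlated with S1_54 minus S0_54 at 0.627 in Joyau, 0.112 in Ae36, -0.212 in Ae54 and -0.193 in Courtot. A gradient between arrays that also parts the 2 Joyau arrays may account for part of it, since their difference also correlated at 0.457 with S1_54 minus mix54 and at 0.386 with S0_36 minus S0_54. A difference between selfed generations, which the design names, stays open and was not separated from that gradient.

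Some transcripts in the mixes lay above both parents, which a sum of parental RNA does not give. In mix54 224 probe sets did so by 1 log2 unit or more, above the 110 to 135 of 20 simulated mixtures with the spread of the fit. This was not beyond the bound of 2 times set beforehand, so the test did not decide on array noise. The simulated mixes carried the spread of the plant groups, while the 2 arrays of mix54 differed by an SD of 0.117 and those of mix36 by 0.131. The bound was thus set against too wide a spread. In mix36 the 44 observed lay below the simulated 91 to 144. Below both parents lay 30 in mix54 and 14 in mix36, under the simulated 63 to 94 and 45 to 70. The excess in mix54 thus lay on 1 side. This and the close agreement of the mix arrays argue against noise between the mix arrays. An error common to both arrays of a mix, or of the parental arrays, was not separated. A Joyau RNA in the mixes that differed from that on the Joyau arrays also stays open: the deviations of the mixes from their mid-parents correlated at 0.270, against a simulated 0.0952 to 0.180, short of the bound that would have decided it. The simulated correlations rest on the same wide spread. No biological explanation was tested, since the mixes are pools of RNA.

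The Ae weight was larger in mix36, at 0.552, than in mix54, at 0.375, although the labels give equal amounts of parental RNA. The bright hybridization controls of Ae36 replicate 2 are argued against, since the weight of mix36 was 0.526 with Ae36 replicate 1 as the only Ae36 array. Unequal amounts of Joyau and Ae RNA in the mixes are a candidate explanation. They require the same gap over probe sets higher in either parent, and the gaps were 0.175 and 0.173, a difference of 0.00187. Any other overall shift in the Ae share would give equal gaps too, so the match does not single out unequal amounts. Unequal amounts alone would also give equal weights within a mix over both sets of probe sets. The weights were instead 0.581 over those higher in Joyau and 0.485 over those higher in Ae36 in mix36. In mix54 they were 0.406 and 0.312, so unequal amounts alone do not account for all of the weights. No biological explanation was tested.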

How the results depend on the processing

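The averaging of the mix arrays and the centring of arrays were chosen after seeing the data. The fit with separate mix arrays was the one planned, and was made an alternative to the averaging after seeing the data. The other alternatives were planned. With an intensity trend and robust prior and with no filter, every count of probe sets stayed within 1.5 times its main value. The counts of the 11 comparisons also did so after quantile normalization and centring. Of the expression classes, 2 did not after quantile normalization, and none was computed after centring. Of 287 calls of single genes, 213 held without the filter, 180 with only the compared groups, 233 with 1 variance and Bonferroni adjustment, 282 after quantile normalization, 277 after centring, 277 with array weights and 287 with the trend or with separate mix arrays. The replicate block ended 3 and the filter on mean values 2 of the calls they could test. Against the computed mid-parents 104 held, 26 did not pass and 5 turned at 1:1, and 107 held, 24 did not pass and 4 turned at 2:1, the only settings to turn a direction. Leaving out 1 array, 242 held at the lowest and 237 at the highest difference. GCRMA's floor limits what dim probe sets can show, and 2 arrays per group limit the rest. Where a cause is not named below, the cause was not tested.

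The filter on mean values left 9353 probe sets, so fewer could pass. It called 5673 for Joyau minus Ae36, 5351 for Joyau minus Ae54, 2041 for Ae36 minus Ae54, 1031 for S0_36 minus mix36, 2196 for S1_54 minus mix54, 933 for S1_54 minus S0_54, 2081 for S0 minus mix over both crosses, 177 for the cross difference, 396 for S0_36 minus S0_54 and 2406 for Courtot. Its Joyau-like, Ae-like, between and above-both classes held 2069, 1187, 1363 and 362 in S0_36, 1845, 1157, 1171 and 249 in S0_54, and 2111, 1041, 1262 and 399 in S1_54. The median of mix54 minus its mid-parent, -0.0105 in the main setting, became 0.0483. After quantile normalization the below-both class held 884 in S0_36 and 455 in S0_54, and the mix minus mid-parent medians were -0.189 for mix36 and -0.136 for mix54.

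With only the compared groups, which leaves fewer degrees of freedom, 1057 passed for Ae36 minus Ae54, 972 for S0_36 minus mix36, 0 for S0_54 minus mix54 (limma, 5527 at an unadjusted p under 0.05), 0 for S1_54 minus mix54 (5723) and 614 for S1_54 minus S0_54. With array weights 1944 passed for Ae36 minus Ae54, 3708 for S1_54 minus S0_54, 774 for the cross difference and 2766 for S0_36 minus S0_54. With an added log2 difference of 1, 2158 passed over both crosses and 2714 for Courtot, and the below-both classes held 182, 131 and 646 in S0_36, S0_54 and S1_54. With 1 variance and Bonferroni adjustment 5785 passed for Joyau minus Ae36, 5348 for Joyau minus Ae54, 1156 for Ae36 minus Ae54, 881 for S0_36, 534 for S0_54 and 1049 for S1_54 against their mixes, 626 for S1_54 minus S0_54, 1012 over both crosses, 868 for S0_36 minus S0_54 and 1523 for Courtot. With these 2 changes together the side with more calls turned, to 586 higher and 570 lower for Ae36 minus Ae54, 294 and 240 in S0_54, 667 and 382 in S1_54 and 732 and 149 in S0_36 against their mixes, 645 and 367 over both crosses, 513 and 113 for S1_54 minus S0_54, and 657 and 866 for Courtot. It also turned with only the compared groups, to 675 and 297 for S0_36 minus mix36 and 384 and 230 for S1_54 minus S0_54, with no filter, to 1912 and 1698 for Ae36 minus Ae54 and 693 and 601 for S1_54 minus S0_54, with the filter on mean values, to 88 and 89 for the cross difference, and with the added log2 difference, to 624 and 594 for S1_54 minus S0_54. Quantile normalization and centring turned it for Joyau minus Ae36 (5490 and 5645, 5373 and 5783), Joyau minus Ae54 (5048 and 5459, 5082 and 5431) and S1_54 minus S0_54 (846 and 680, 945 and 472), and centring alone for Ae36 minus Ae54 (1844 and 1760), S0_36 minus mix36 (1267 and 1237) and Courtot (2481 and 2543).

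Against the computed 1:1 mid-parent 4936 passed for S0_36, 2889 for S0_54, 6555 for S1_54 and 6510 over both crosses, and against the 2:1 mid-parent 4679, 2667, 6196 and 5917, references whose error comes from 2 arrays per parent. Directions turned at 1:1 for LOC606328 (-0.19 in S0_54, -0.82 in S1_54), LOC543330 (0.55 in S0_54), LOC543261 (0.34 in S0_54), LOC543338 (-0.11 in S1_54) and FBP, not called in the main setting (-0.12 over both crosses). At 2:1 they turned for LOC543330 (1.00 in S0_54, 0.39 over both crosses), LOC543261 (0.57 in S0_54), LOC606328 (-0.24 in S1_54) and FBP (-0.0448). With the mix arrays as separate samples, which adds samples that vary little, 5598, 4442 and 7417 passed for S0_36, S0_54 and S1_54 against their mixes, 3269 for S1_54 minus S0_54, 7194 over both crosses, 1945 for the cross difference and 2190 for S0_36 minus S0_54.

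Replicate numbers 1 and 2 are shared by the parents and Courtot. The deviations of same-numbered arrays correlated at 0.0760, 0.228 and 0.114 among the parents and at 0.0542, -0.0564 and 0.00818 with Courtot. These values are low, but all are positive among the parents. Replicate 2 minus replicate 1 also correlated with S1_54 minus S0_54 at 0.627 in Joyau, 0.112 in Ae36, 0.212 in Ae54 and 0.193 in Courtot. A difference tied to the replicate number is therefore not excluded. A replicate block among the parents gave 10042 for Joyau minus Ae36, 9364 for Joyau minus Ae54 and 2091 for Ae36 minus Ae54. No paired analysis was possible for the other comparisons because the groups share fewer than 2 numbers.

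Leaving out 1 array at a time, where the lone array of a group is assumed to vary like the other groups, gave 1319 to 2395 for S0_36 minus mix36, 845 to 1779 for S0_54 minus mix54, 1784 to 3826 for S1_54 minus mix54, 96 to 1224 for S1_54 minus S0_54, 248 to 464 for the cross difference, 605 to 1011 for S0_36 minus S0_54 and 1996 to 4669 for Courtot. The lowest values came without S0_36 replicate 3 in S0_36 minus mix36, the cross difference and S0_36 minus S0_54, without S0_54 replicate 4 in S0_54 minus mix54, without S1_54 replicate 5 in both S1_54 comparisons and without Courtot replicate 1. The side with more calls turned for Ae36 minus Ae54 without Ae36 replicate 2 (1735 higher, 1249 lower) and without Ae54 replicate 1 (1275 and 1055), for S0_36 minus mix36 without S0_36 replicate 9 (883 and 642), for S0_54 minus mix54 without S0_54 replicate 3 (457 and 453), for S1_54 minus S0_54 without S0_54 replicates 3 and 4 (103 and 42, 250 and 110) and without S1_54 replicate 5 (70 and 26), and for Courtot without Courtot replicate 2 (1588 and 1671). The classes ranged from 1689 to 2687 (between) and 269 to 668 (below both) in S0_36, from 1299 to 2141 (Ae-like), 1167 to 1978 (between), 315 to 457 (above both) and 110 to 241 (below both) in S0_54, and from 527 to 837 (above both) and 616 to 1134 (below both) in S1_54. Both crosses together gave 2504 to 3606 and the parental comparisons stayed within 1.5 times their counts. The Ae weight difference between S0 and mix of -0.0867 was -0.111 after quantile normalization, -0.0366 with the filter on mean values and -0.000371 on the log2 scale. With the mixes averaged its exact permutation p cannot fall under 0.0667, the value reached after quantile normalization, so that no such setting could pass, and p ranged from 0.0667 to 1. List tests and their alternatives were not run, since no list had 5 tested probe sets.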

Other observations

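All of the following comparisons were chosen after the data were seen. Differences between the donor accessions were partly seen between the synthetics. Of 2616 probe sets that differed between Ae36 and Ae54 by a log2 value of 1 or more, 2007 (76.7%) had the same sign between S0_36 and S0_54, against 2032 (77.7%) between the mixes, with slopes of 0.296 and 0.438. Of the 1359 probe sets called between S0_36 and S0_54, 479 were called between the donors in the same direction, 148 in the opposite direction and 732 not at all. LOC542898 was at 12.44 in Ae36, 11.91 in mix36 and 11.38 in S0_36, and at 4.56, 4.07 and 4.04 in Ae54, mix54 and S0_54. Where Joyau was below a log2 value of 4, 647 of 810 probe sets (79.9%) kept the sign. Other genes left both parents. LOC606323 was at 7.88 ± 0.35 in S0_54 (SD, n = 2), although Joyau was at 3.02 and Ae54 at 3.60, and at 4.94 in S1_54. LOC542888 was at 7.54 ± 0.53 in S0_54 with Joyau at 2.48 and Ae54 at 2.83, and at 2.86 in S1_54. Both were high in the other cross: LOC606323 was at 11.03 in Ae36 and 11.49 in S0_36, and LOC542888 at 7.85 and 9.94. Why S0_54 showed them was not tested.

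Few transcripts that only 1 parent showed were dim, at 3.5 or less, in the synthetics. A value above 3.5 does not show that the level was retained. The median over probe sets shown by Ae36 alone was 7.70 in mix36 and 6.75 in S0_36. Over those shown by Joyau alone it was 7.00 and 7.28. In cross 54 these medians were 6.94 and 6.77 for Ae54, and 7.51 and 7.46 for Joyau. LOC543416, at 7.86 in Joyau and 3.50 in S0_36, was not counted, since Ae36 at 3.64 exceeded 3.5. Of 432 probe sets bright in Joyau (7 or more) and dim in Ae36 (3.5 or less) that mix36 showed above 5, 7 were dim in S0_36, LOC543016 among them, at 9.82 in Joyau and 2.83 in S0_36. None of the 350 shown by Ae36 alone and by mix36 was dim in S0_36, a count of 0. In S0_54, 4 of 427 Joyau probe sets were dim (Ta.10691.1.A1_x_at, Ta.28584.1.A1_at, Ta.28842.1.S1_at and TaAffx.37806.1.A1_at) and 1 of 250 from Ae54 (TaAffx.71647.1.A1_at). In S1_54 these numbers were 7 and 6. Of 291 probe sets shown by Ae54 alone, mix54 showed 250 above 5, and the others were not counted. Mix36 showed 350 of the 351 from Ae36 above 5. Ta.28584.1.A1_at, Ta.28842.1.S1_at and TaAffx.37806.1.A1_at were dim in all 3 synthetic groups. TaAffx.37806.1.A1_at was at 8.27 in Joyau and 6.67 in mix36, and at 1.70 in S0_36, 1.72 in S0_54 and 1.70 in S1_54. LOC543016 varied between plants, with an SD of 4.09 around a mean of 5.66 in S0_54, and was at 8.73 in S1_54 and 2.80 in Courtot.

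Among all tested probe sets, 4974 were higher in Ae36 and 5865 in Joyau, and 4753 were higher in Ae54 and 5417 in Joyau. Of the probe sets lower in S0_36 than in mix36, 53.4% were higher in Ae36 than in Joyau and 37.0% higher in Joyau. Of the 1027 lower in S0_54 than in mix54, 30.3% were higher in Ae54 and 513 were higher in Joyau. For S1_54 minus mix54 no side stood out, with 31.8% and 36.9% of the lower calls and 27.1% and 27.3% of the higher calls. The mixes themselves differed in Ae weight, at 0.552 and 0.375, and these shares were not tested against each other.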
